A study of Mus musculus with 2 samples.

How the data were processed

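Xenium In Situ decodes single RNA molecules in a tissue section and assigns them to segmented cells. It was run on 1 section of EKP tumour and 1 section of RKP tumour from mice 5 weeks old, per the labels' protocols, with paraffin-embedded tissue and a panel of 479 genes, 20 negative control probes, 41 negative control codewords and 1 unassigned codeword. The authors deposited, for each section, a matrix of raw transcript counts per feature and cell, with no normalization; the file headers name Xenium software without a version. Seurat 4.4.0 is named in the submitters' processing notes with no stated role. The segmentation method, any quality limit on transcripts and the positions of cells are not given in the sources used here, so no distance between cells was computed; the closing section uses the order of cells in the file as a partial stand-in for place. Segmentation can assign transcripts of neighbouring cells to a cell, which limits every comparison within a cell class.

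Sections were grouped by their titles. With 1 section per group no test between groups is possible, and all values describe these sections. The comparisons were of whole sections, of the shares of cell classes, and of genes within the Krt8-rich, macrophage-, fibroblast- and T cell-like cells. The main settings, lists and the rule for named genes were fixed before the data were examined. The Krt8-rich class was not: the class fixed in advance for the injected lines was the epithelial-like one. Whole sections were compared on counts summed over all cells and scaled to 1000000 gene counts (CPM). A gene was kept when its sum was above that of the highest negative control probe (311 in EKP, 162 in RKP) in at least 1 section, and where the lower section was at or below that level, the level took its place and the fold is a lower bound; with 1 to 3 counts the ratio or the counts are given instead. Within a class, the same rule used the class's cells. Ratios have exact 95% conditional binomial intervals and shares have Clopper-Pearson 95% intervals; both cover counting error only. A difference was counted at 2-fold, or 1.5-fold for shares of classes, which is a rule of size and not a test. For a count of 0, the floor was 3 counts.

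Cells with 20 or more gene counts (191692 in EKP and 248060 in RKP) were scaled to the median cell total, log-transformed and centred, reduced to 30 principal components, joined to 15 nearest neighbours and clustered together by the Leiden method at resolution 1, which gave 18 clusters. A cluster was named from marker lists fixed in advance when at least 3 markers of 1 class, and no fewer than 1 in 2 of those measured, stood at 100 CPM or more and 2-fold above the median cluster. A cluster whose mean log2 score for another class lay within 0.5, or whose median count was under 0.5 of that of all cells with no marker among its 10 leading genes, stayed unnamed. These naming limits were set after the data were seen. Clusters with Krt8 at least 2-fold above the median cluster, no score of 1 or more for a stromal or immune class and no low counts were pooled as Krt8-rich, because some of them had almost no Epcam and could not be named epithelial; they were clusters 0, 3, 4, 10 and 14. Doublets were not called. Named classes carry the word "like" because a cluster was named from its genes alone. Within the macrophage-, fibroblast-, T cell-, endothelial- and neutrophil-like classes, a gene counted only if its level in the class was at least that in the other cells of the section where it was higher.

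For each of 30 gene lists with 3 or more kept members, the median log2 ratio was placed among 10000 random lists of the same size, matched on abundance in 5 bins; lists outside the 2.50 to 97.5 percentiles were reported. Genes overlap between lists. The text names the 12 kept genes with the largest ratio in each direction for whole sections and for Krt8-rich cells, 6 in each direction for other classes, up to 5 members per list as examples, and Cdh1 and Trp53. Genes named beyond this rule, including those under the 1000 CPM limit, the genes of the Epcam-high and Epcam-low clusters, single markers and the core genes of each class, were chosen after their values were seen. For detection of single genes, each cell with 40 or more counts was thinned at random to 40.

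The alternatives fixed in advance were other scalings (counts per cell, median of ratios, totals without the 10 most abundant genes, every cell weighted alike), cells with 20 or more counts, subtraction of the negative control level, no filter, cell filters of 10 and 40 counts, resolutions of 0.5 and 2, clustering on cells thinned to 40 counts, and clustering each section by itself. Chosen after seeing the data were a 1000 CPM limit, cells with 80 or more counts, shares without the low-count unnamed clusters, and a mixed macrophage and fibroblast cluster counted as immune. The closing section gives their effect.

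The steps were tested on simulated data. Of genes simulated 3-fold apart, 49 of 49 and 50 of 50 passed 2-fold, none of 49 and of 50 at 1.5-fold and none of 275 equal genes did, and 95.8% of intervals held the simulated ratio. Of 100 random lists 8% lay outside the middle 95%, and 10 of 10 lists simulated 3-fold higher did. Among 12000 simulated cells of 6 classes, 98.6% fell in a cluster with the right name. Those classes were built by raising the markers that the naming rule scores, at mean depths of 80 and 160 counts. They held no transcripts of neighbouring cells, no section difference and no Krt8-rich rule. The value thus says little about naming in these sections, where 38.0% of EKP cells had under 40 counts. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Gene positions are from the GRCm38 annotation. Control features were left out of all gene comparisons, and their counts are given in the closing section.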

Results

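The series measured RNA in place, with the Xenium In Situ platform, in sections of subcutaneous mouse tumours labelled as diffuse gastric cancer. Its title concerns lineage plasticity and immune remodelling of diffuse gastric cancer driven by a mutant form of RHOA, a small GTPase that controls the actin cytoskeleton. A pair of cultured mouse lines, labelled EKP and RKP, gave the tumours. The labels do not spell the letters out and do not say which line carries the mutant RHOA. Cultured cells of each line in Matrigel, a basement membrane gel, were injected under the skin of both flanks of C57BL/6 mice, and tumours were taken at similar final volumes. There was 1 section of EKP tumour and 1 of RKP tumour, prepared as 1 paraffin block on 1 slide. No replicates exist, so every difference described here is a difference between 2 sections, with no p-value, and every interval covers counting error only.

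The panel held 479 genes, 379 from a mouse tissue panel and 100 added ones. The section labelled EKP held 261111 segmented cells with 31597828 gene counts in total, and the section labelled RKP held 255744 cells with 44294494. The median cell had 84 counts in EKP and 154 in RKP. Cells with under 20 counts made up 26.6% of the EKP section (Clopper-Pearson 95% interval 26.4 to 26.8) and 3.00% of the RKP section (2.94 to 3.07). Negative control probes, which match no mouse transcript, gave 50.1 counts per 1000000 gene counts in EKP and 15.7 in RKP.

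**Figure D1:**
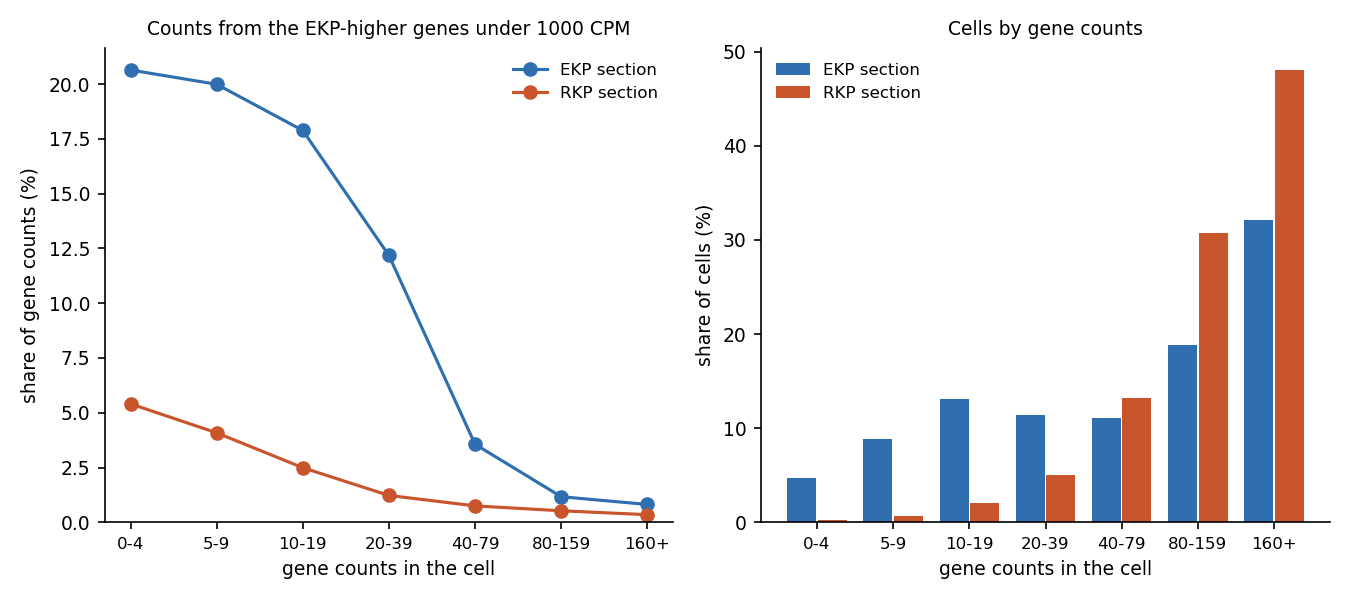
Left, the share of gene counts (%) that came from the 152 genes at least 2-fold higher in EKP and under 1000 counts per 1000000 gene counts, against the gene counts of the cell, with 1 line per section. It was 20.6% in EKP cells with under 5 counts and 0.816% in those with 160 or more; the RKP values were 5.41% and 0.349%. Right, bars give the share of cells (%) in each depth class.

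The first comparison asked how the genes that the title and the names of mouse gastric cancer models point to stood in both sections. Cdh1 (ENSMUSG00000000303, chromosome 8, 106603350 to 106670247 in GRCm38), the epithelial cadherin of adherens junctions, stood at 9357 counts per 1000000 gene counts (CPM) in EKP and 9422 in RKP, a ratio of 1.01 (1.00 to 1.01). Trp53 (ENSMUSG00000059552, chromosome 11, 69580348 to 69591873), the tumour suppressor p53, stood at 1685 CPM in EKP and 1580.2 in RKP, a log2 ratio of -0.09. As counts per cell without scaling, which moves all genes alike, the log2 ratios were 0.53 for Cdh1 and 0.42 for Trp53. Rhoa was not on the panel. Where the probes lie relative to any engineered change is not given in the sources used here, so these levels do not check the labels.

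Across the whole sections, 39 of 477 kept genes were at least 2-fold higher in RKP, and the 12 with the largest ratios follow. Cldn2, a pore-forming claudin of tight junctions, was 11.0-fold higher in RKP (10.8 to 11.2; 503 against 5530.0 CPM). Prom1, a membrane protein of stem-like and apical epithelial cells, was 3.84-fold higher (3.81 to 3.87), the membrane mucins Muc20 and Muc4 were 4.23-fold and 3.68-fold higher, and the GABA receptor subunit Gabrp was 7.11-fold higher. Sftpd, the collectin known as surfactant protein D, was 15.3-fold higher (14.4 to 16.3; 35.7 against 546 CPM), and Ambp, the precursor of alpha-1-microglobulin and bikunin, was 7.40-fold higher. Krt5, the keratin of basal squamous cells, was 13.8-fold higher (13.2 to 14.5; 55.9 against 774 CPM), beside Krt79 at 7.30-fold, the epidermal calmodulin-like Calm4 at 5.82-fold and the desmosomal cadherin Dsc3 at 3.94-fold. The muscle calcium buffer Pvalb completed them, at 3.74-fold. Several moved with the setting, as log2: with every cell weighted alike and in cells of 80 or more counts, Sftpd stood at 2.78 and 5.83, Krt5 at 3.05 and 5.73, Ambp at 1.71 and 4.93, and Pvalb at 0.91, under 2-fold, and 4.05.

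In the other direction, 166 genes were at least 2-fold higher in EKP and 272 lay in between. The 12 with the largest ratios stood at 56.3 to 101 CPM in EKP, and several are genes of brain, airway, kidney or liver. They included the neuronal transcription factor Myt1l (22.0-fold, 19.1 to 25.6), the AMPA receptor subunit Gria2 (16.2-fold), the ciliary dynein chain Dynlrb2 (17.5-fold), the lacrimal gene Prol1 (16.0-fold), Lamp3 (15.5-fold) and Cd5l, a protein secreted by macrophages (15.2-fold). For the other 6, the RKP level lay within the background of the negative control probes, so the fold is a lower bound. They were 9530003J23Rik (at least 19.5-fold), the airway secretoglobin Scgb3a2 (at least 19.0), the kidney gene Kl (at least 17.4), the fatty acid transporter Slc27a2 (at least 15.5), the potassium channel gene Kcnj16 (at least 15.4) and the liver bile acid transporter Slc10a1 (at least 15.4). The 152 genes of this kind took a larger share of the counts in EKP cells with few counts, as the plot of counts by cell depth shows, although 184086 of their counts in EKP lay in cells with 160 or more. In cells of 80 or more counts the 12 genes named stood nearer, from log2 -3.07 for Cd5l to -1.32 for Scgb3a2, with Myt1l at -1.98 and Gria2 at -1.60.

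Among the 176 genes with at least 1000 CPM in the higher section, a limit chosen after the values were seen, 14 were at least 2-fold higher in EKP and 16 in RKP. The EKP genes included Ivl, a protein of the cornified envelope (4.58-fold), the matrix protein Dpt (3.23-fold), the gastrointestinal glutathione peroxidase Gpx2 (3.02-fold), the secreted WNT antagonist Sfrp1 (2.83-fold), the proteoglycan Acan (2.82-fold), the elastic fibre protein Mfap5 (2.42-fold) and the gelatinase Mmp2 (2.14-fold). The RKP genes included the growth factor Ptn (3.55-fold), the transcription factor Sox9 (2.53-fold) and Lgr5, a receptor that marks gut stem cells (2.04-fold).

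**Figure D2:**
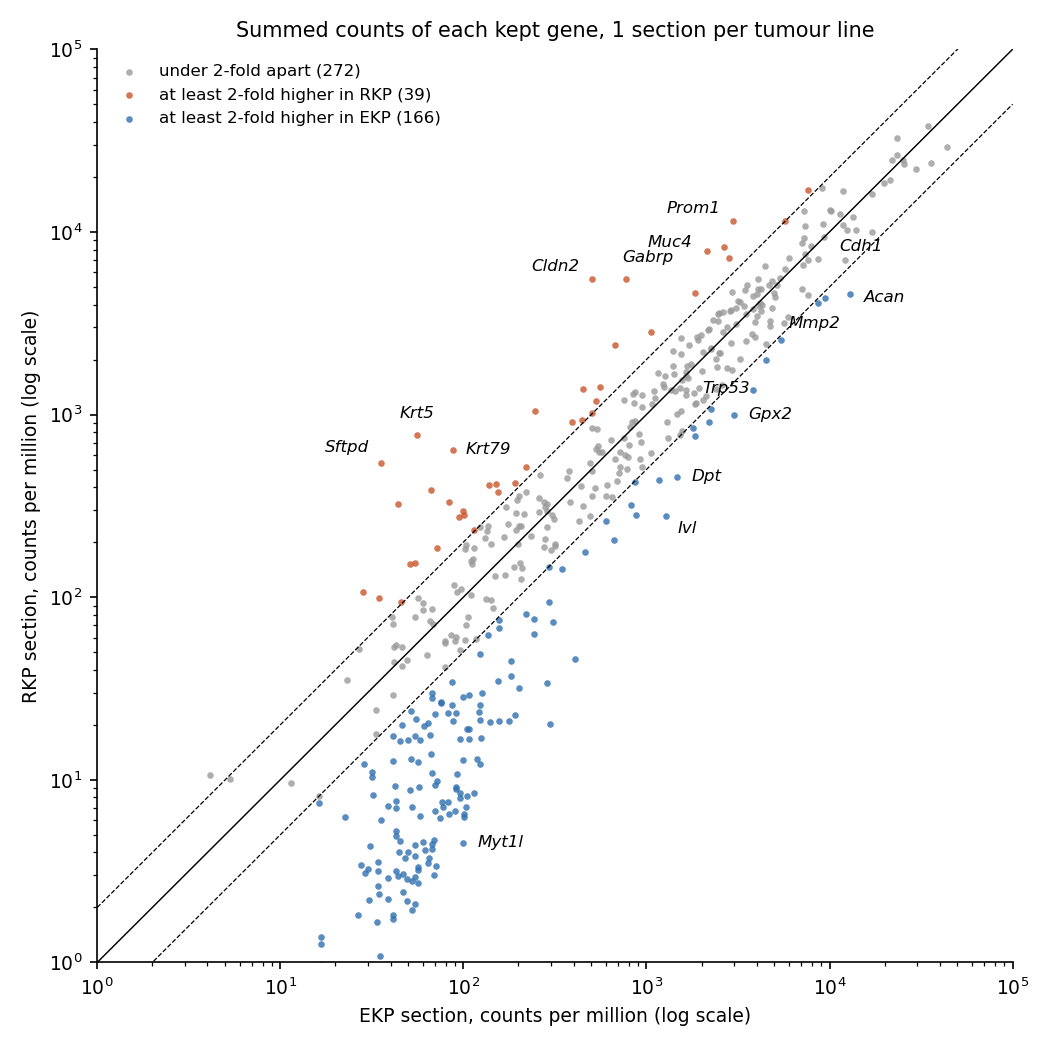
Each point is 1 of 477 kept genes, placed by its summed counts per 1000000 gene counts in the EKP section (x, log scale) and the RKP section (y, log scale). The solid line marks equal levels and the dashed lines a 2-fold difference; Sftpd, Krt5 and Cldn2 lie farthest above at 15.3, 13.8 and 11.0-fold, and Myt1l lies below at 22.0-fold higher in EKP.

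Of 30 gene lists fixed in advance, 22 had 3 or more kept members, and 5 had a median ratio outside the middle 95% of matched random lists. The WNT and stem list lay above them, with 3 of 6 members at least 2-fold higher in RKP, 1 higher in EKP and a median log2 ratio of 0.83. Its members Prom1 and Sox9 stood at log2 1.94 and 1.34, Sfrp1 at -1.50, and the abundant hyaluronan receptor Cd44 at 0.49. The squamous and basal list also lay above, with Krt5 and Dsc3 higher in RKP, Ivl higher in EKP and a median of 1.98 over 3 members. It lay within the random range, with a median of 1.01, when every cell was weighted alike. Below lay the fibroblast list (median -0.80), with Dpt and Mfap5 at log2 -1.69 and -1.28 and 4 of 6 members in between. The matrix list had 1 of 8 members, Mmp2, at least 2-fold higher in EKP. Its median was -0.51 and Col1a1, the main fibrillar collagen, stood at -0.58. The hypoxia and angiogenesis list had 1 of 5 members, the hypoxia-responsive Ndrg1 at log2 -1.12, past 2-fold, while Hif1a stood at 0.12; the median was -0.69. It lay within the random range when every cell was weighted alike (median -0.49), at 1000 CPM or more (-0.49) and in cells of 80 or more counts (-0.66). The gastric and gut list lay within the range, with 4 members higher in RKP, 6 in EKP and a median of -0.11 (percentile 82.8). As counts per cell and with median-of-ratios scaling, which move all genes alike, the median was 0.40 and 0.32 and the percentile 87.5 and 88.0. It lay above the range at 1000 CPM or more (0.62) and in cells of 80 or more counts (0.44). T cell genes had a median of 0.80 (Ctla4 1.14, Cd3e 0.84) and the cell cycle genes of the proliferation list a median of 0.47 with 5 of 5 members in between, both within the middle 95%.

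The scale moved these values. The median log2 ratio over all kept genes was -0.43 with totals as the scale and 0.08 as counts per cell, so list medians moved by that shift alone: that of the matrix list went from -0.51 to 0.01 while its percentile among random lists was 0.54 and 0.55. As counts per cell, 83 genes were at least 2-fold higher in RKP and 133 in EKP; with median-of-ratios scaling the counts were 68 and 137.

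The next comparison asked which kinds of cell made up each section. Cells rich in the simple epithelial keratin Krt8, the class used for the injected lines, made up 25.7% of EKP cells and 44.3% of RKP cells with 20 or more counts. The difference of 18.6 percentage points narrowed to 3.13 with finer clusters and 0.663 with each section clustered by itself. An unnamed cluster with low counts, left out of the class, had Krt8 at 63328 CPM and Epcam at 55500 CPM and held 23237 EKP and 1569 RKP cells, so the share of the injected lines is not settled by this class. Macrophage-like cells made up 8.52% and 15.1%, and T cell-like cells 0.923% and 1.85%, a 2.00-fold difference. With each section clustered by itself the RKP minus EKP differences of both turned to -9.47 and -6.42 percentage points. That setting called 9.24% of EKP cells T cell-like, although Cd3e was detected in only 2.06% of EKP cells with 20 or more counts. Most of those EKP cells thus had no Cd3e count. In RKP Cd3e was detected in 3.87%, while finer clusters called 10.5% of RKP cells T cell-like, so most of those had none either. With a filter of 40 counts, 8.32% of EKP and 10.9% of RKP cells were called T cell-like, and most of them had no Cd3e count. Fibroblast-like cells were 2.29-fold more frequent in EKP (8.26% against 3.60%), and 1.12-fold (7.34% against 6.56%) with each section clustered by itself. Endothelial-like cells made up 8.40% of EKP and 5.97% of RKP cells, and neutrophil-like cells 10.3% and 9.13%, a difference that turned to 0.0373 and 0.150 percentage points higher in RKP with coarser and finer clusters. A squamous epithelial-like cluster led by Calm4, Dsc3, Krt5 and Krt79 held 4187 RKP cells (1.69%, 1.64 to 1.74) and 3 EKP cells (0.00157%). With cells thinned to 40 counts before clustering, the class held 5613 RKP cells (2.39%) and 2359 EKP cells (1.46%), 1.64-fold apart. Krt5 was detected after thinning in 1.93% of RKP but 0.164% of EKP cells, so most of those EKP cells had no Krt5 count. Of the 7 named classes, 5 differed in share by 1.5-fold or more. Clusters left unnamed held 37.9% of EKP cells and 18.3% of RKP cells.

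Macrophage-, neutrophil- and T cell-like cells together made up 19.7% of EKP and 26.1% of RKP cells, a difference of 6.37 percentage points (6.01 to 6.72 between the outer limits of both shares). In the main clustering, macrophage-like cells took 43.2% of them in EKP and 58.0% in RKP, and neutrophil-like cells 52.2% and 34.9%. With finer clusters the macrophage-like part was larger in EKP (35202 of 56957 cells against 49535 of 95059 in RKP). With each section clustered by itself it was too (26200 of 62527 against 10415 of 38401). The neutrophil-like part was then larger in RKP (18609 and 20978 of the same totals). The other clusterings and cell filters fixed in advance kept both directions. The direction of the summed share hung on the clustering: it turned to -17.1 points when each section was clustered by itself. In that setting unnamed clusters held 7.69% of EKP and 34.8% of RKP cells, against 37.9% and 18.3% in the main one, which bears on the macrophage- and T cell-like shares as well. The difference was 2.10 points when an unnamed cluster with macrophage and fibroblast genes, among them Retnla, Folr2 and Lyve1, was counted as immune. An unnamed cluster with epithelial and macrophage genes, of 0.703% of EKP and 4.16% of RKP cells, was not counted. Counting it would widen the difference. The share ranged from 13.5% to 25.9% over 10 successive parts of the EKP file and from 13.6% to 36.2% in RKP.

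**Figure D3:**
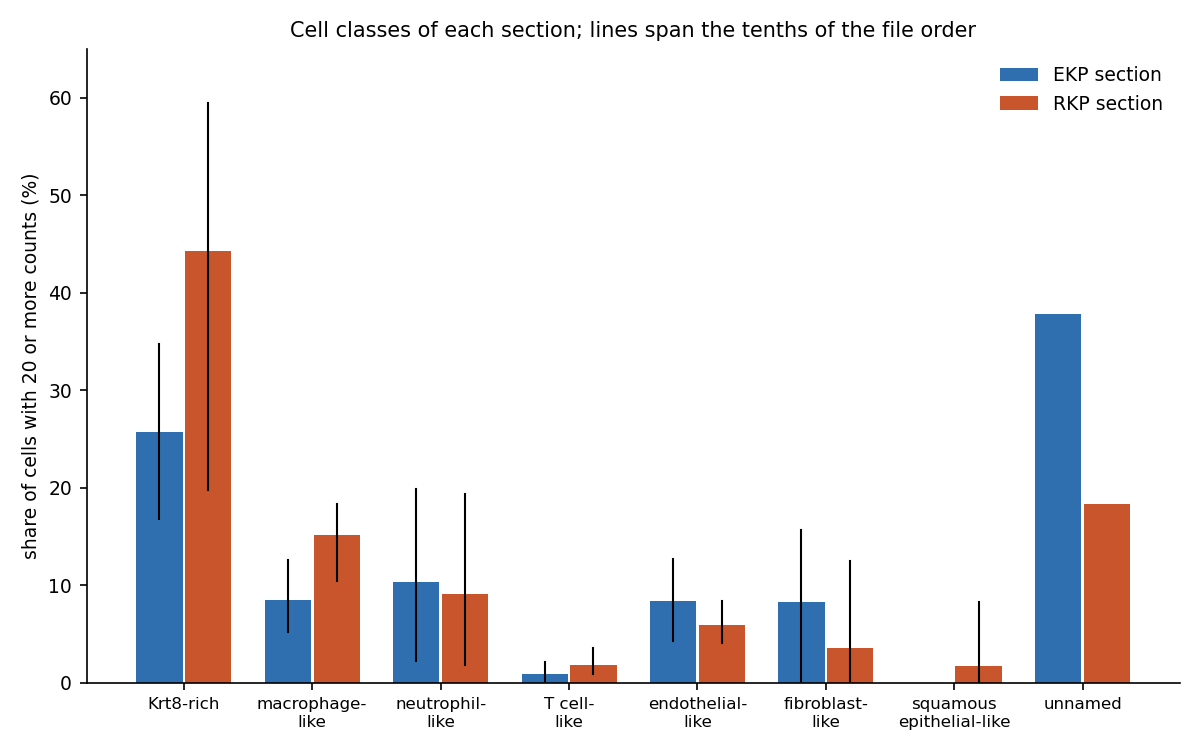
Bars give the share (%) of cells with 20 or more counts in each cell class, for the EKP and RKP sections. Black lines span the lowest to the highest share over 10 successive parts of each file and are not a replicate error; Krt8-rich cells took 25.7% in EKP and 44.3% in RKP, and squamous epithelial-like cells 0.00157% and 1.69%.

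Single marker genes were also counted after each cell with 40 or more counts was thinned to 40, which needs no clustering and gives every cell the same depth. The filter of 40 counts by itself had brought the median depth to 165 in both sections. Arg1, the arginase of alternatively activated macrophages, was detected in 21.3% of EKP and 37.7% of RKP cells, against 12.8% and 28.3% within Krt8-rich cells. Shares within Krt8-rich cells are given as a reference. They rest on the clustering, and whether they come from transcripts of neighbouring cells or from these cells was not tested. Cd3e, a T cell receptor subunit, was detected in 1.06% and 1.96% of cells (0.258% and 0.620% within Krt8-rich cells), the checkpoint receptor Ctla4 in 0.665% and 1.61% (0.137% and 0.437%), and Cd8a, of cytotoxic T cells, in 0.694% and 0.873% (0.219% and 0.538%). The macrophage genes Cd68 (14.6% and 15.7%) and Mrc1 (14.04% and 13.8%) and the neutrophil genes Csf3r (9.52% and 8.54%) and Cxcr2 (4.18% and 4.401%) were closer. Pecam1, of endothelium, was detected in 7.03% and 4.48%, and Lum, of fibroblasts, in 19.99% and 14.5%. The cell cycle genes Mki67 and Top2a were detected in 7.27% and 7.75% of EKP cells and in 10.7% and 10.8% of RKP cells. The filter of 40 counts left out 38.0% of EKP and 8.07% of RKP cells.

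Krt8-rich cells were compared because they bear on the lineage state of the injected lines. Ambp was 80.5-fold higher in RKP (65.1 to 101; 7.08 against 570.0 CPM) and Sftpd 75.1-fold (64.1 to 88.6). The intestinal mucin Muc3a (31.3-fold), the vitamin D-binding protein Gc (17.01-fold), Tm4sf4 (14.05-fold), the brush-border cadherin Cdhr5 (13.5-fold), Agr2, a folding enzyme of mucous cells (12.3-fold), and the antimicrobial lectin Reg3g (8.66-fold) followed. Ambp, Sftpd, Muc3a, Gc, Tm4sf4, Cdhr5 and Agr2 were leading genes of a single cluster of 15 EKP and 11067 RKP cells, whose origin is not settled; outside it Ambp stood at 29.1 CPM in EKP and 33.5 in RKP. Cldn2 was 8.81-fold higher (1046 against 9211 CPM) and Ptn, a heparin-binding growth factor, 15.5-fold (229 against 3539 CPM). Krt5 (11.0-fold), the mast cell protease Cpa3 (16.7-fold) and Reg3g stood higher still in other RKP cells, at 1499, 242 and 161 CPM.

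In EKP, the Krt8-rich cells stood higher in Ptprn2 (8.21-fold, 417 against 50.7 CPM), Scg2 (7.34-fold) and Snap25 (3.94-fold), proteins of secretory granules and their release. They also stood higher in Ivl (7.20-fold, 2528 against 351 CPM), in Gpx2 (4.04-fold, 6109 against 1513 CPM), in the actin-severing Scin (3.76-fold) and in Ecrg4 (4.07-fold). The mucins Muc5ac, of gastric surface cells (8.46-fold), Muc2, of goblet cells (5.85-fold), and Muc16 (3.81-fold) stood higher in EKP at 66.9, 191 and 144 CPM, beside Dcdc2a (5.33-fold) and Dcpp2 (4.63-fold) at 29.0 and 49.3 CPM. Ecrg4, Muc2, Dcpp2 and Dcdc2a stood higher still in other EKP cells, at 1148, 244, 148 and 38.7 CPM. Cdh1 stood at 17082 CPM in EKP and 13654 in RKP Krt8-rich cells, a ratio of 0.799, and Trp53 at 1021 and 876, below the 2134 and 2409 of the other cells.

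Over 49329 EKP and 109888 RKP Krt8-rich cells, 73 of 459 kept genes were at least 2-fold higher in RKP and 93 in EKP. In the clusters named epithelial alone, the kind of class fixed in advance, the counts were 61 and 99 of 445. Of 22 lists in all Krt8-rich cells, 6 lay outside the middle 95% of random lists. The gastric and gut list lay above (8 of 17 members higher in RKP, 2 in EKP, median log2 0.49), as did the WNT and stem list (4 of 6 and 1 of 6, median 1.10; Lgr5 2.06, Prom1 1.62, Sfrp1 -1.84). The actin and contraction list lay below, with 3 of 6 members higher in EKP and a median of -1.06 (Cnn1 -1.53, Tagln -1.46, Acta2 -0.32). So did the matrix (-0.74), mural (-0.92) and endothelial (-1.08) lists, whose genes other cells in the sections express as well. With a 1000 CPM limit, chosen after the values were seen, 23 genes remained higher in RKP and 11 in EKP; with finer clusters the EKP count was 159 and with each section clustered by itself 181.

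The Krt8-rich cells fell into clusters with high and with very low Epcam, a surface marker of epithelial cells; this split was chosen after the clusters were seen. The Epcam-low clusters held 32.6% of the Krt8-rich cells in EKP (32.2 to 33.0) and 36.1% in RKP (35.8 to 36.4). In both sections they had lower Cdh1 (log2 -3.67 in EKP and -3.81 in RKP) and higher S100a4, a calcium-binding protein of motile cells (2.76 and 4.39), Snai1 (1.78 and 2.95) and Snai2 (2.36 and 3.16), the transcription factors of mesenchymal transition. These genes helped to define the clusters, so the values describe them. In Epcam-low cells Ptn stood at 519 CPM in EKP and 11686 in RKP (22.5-fold), and the Notch target Hey1 was 10.9-fold higher in RKP, while Acan (7.53-fold), Sfrp1 (7.02-fold), the keratin Krt19 (5.78-fold) and the contractile Cnn1 (6.23-fold) were higher in EKP. In Epcam-high cells Ptprn2 (72.0-fold), Scg2 (22.5-fold) and the neuroendocrine transcription factor Insm1 (5.51-fold) were higher in EKP, and Ambp (163-fold) and Muc3a (59.7-fold), leading genes of the cluster with 15 EKP cells, in RKP. Of 22 lists in Epcam-low cells, 7 lay outside the random range. The T cell (4 of 4 members higher in RKP, median log2 2.56), NK and cytotoxic (3 of 4, with 1 higher in EKP, 2.12), macrophage (5 of 8, 1.10) and alternative macrophage (4 of 6, 1.46) lists lay above, and Cpa3 was 17.2-fold and Gzmb 8.12-fold higher in RKP. The actin (-1.83), mural (-1.53) and matrix (-0.92) lists lay below. The gastric and gut list (2 of 17 members higher in RKP, 3 in EKP, median -0.17) and the WNT and stem list (median 0.08) lay within. In Epcam-high cells, which include the cluster with 15 EKP cells, 4 lists lay outside: gastric and gut (8 of 16 higher in RKP, 3 in EKP, median 0.83) and WNT and stem (4 of 6, 1.40) above, and matrix (-0.74) and endothelial (-1.12) below. Transcripts of neighbouring cells were not separated from those of the Epcam-low cells.

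**Figure D4:**
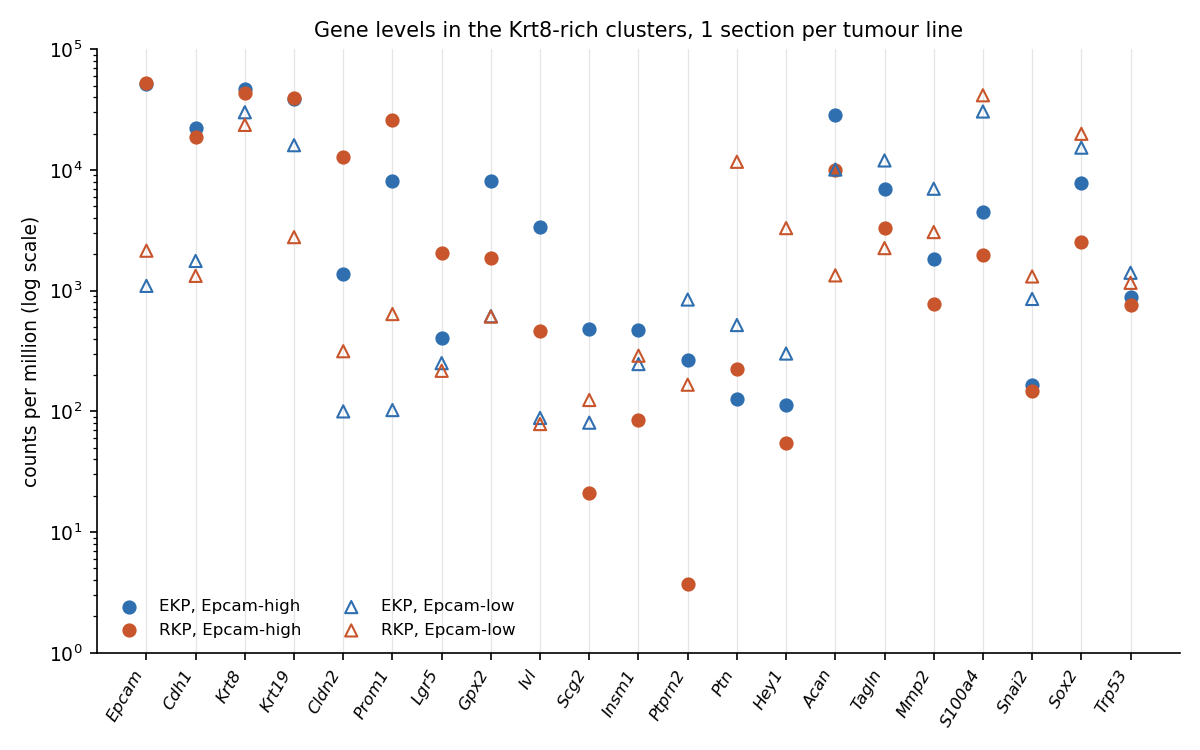
Counts per 1000000 gene counts (y, log scale) of selected genes in the Krt8-rich clusters, with filled circles for Epcam-high and open triangles for Epcam-low clusters of the EKP and RKP sections. Ptn in Epcam-low cells stood at 519 in EKP and 11686 in RKP, and Cdh1 was lower in the Epcam-low clusters of both sections; the genes were chosen after the values were seen.

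Macrophage-like cells were compared for the immune remodelling that the title names. The chemokine Ccl9 was 2.64-fold higher in RKP (2.61 to 2.67), with the collagenase Mmp8 at 2.09-fold, the interferon-induced Ifitm6 at 2.64-fold, the scavenger receptor Marco at 2.37-fold and Pi16 at 2.29-fold. The class pooled a cluster shared by the sections with a cluster led by Mmp8 and Ccl9 that held 1101 EKP and 13034 RKP cells, so these ratios include the mix of the clusters. EKP macrophage-like cells stood higher in the secreted nuclease Dnase1l3 (4.84-fold, 4.57 to 5.12), Hap1 (2.48-fold), the platelet chemokine Ppbp (2.32-fold), the checkpoint receptor Lag3 (2.19-fold) and Il1r2, a decoy receptor for interleukin 1 (2.18-fold). Arg1 and Mrc1, which mark alternatively activated macrophages, had ratios of 1.38 and 1.43, under 2-fold. The class left out unnamed clusters that share leading macrophage genes. That with fibroblast genes, and Mrc1 among its leading genes, held 17397 EKP and 11928 RKP cells. That with epithelial genes and Arg1 held 1347 and 10329. These ratios thus cover the named clusters only. Over all thinned cells, Mrc1 was detected in 14.04% of EKP and 13.8% of RKP cells, and Arg1 in 21.3% and 37.7%. Of 7 lists tested, the actin (median -0.67), mural (-0.79), matrix (-0.54) and checkpoint (-0.35) lists lay below the middle 95% of random lists, with no member of the first 3 past 2-fold. In total 10 of 83 kept genes were 2-fold apart, 5 each way, over 16341 EKP and 37560 RKP cells; the count was 85 with cells of 40 or more counts, of which 80 were higher in EKP, 117 with thinned cells, of which 114 were higher in EKP, and 59 with each section clustered by itself.

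Fibroblast-like cells of the RKP section carried skeletal muscle transcripts: Pvalb was 76.4-fold higher (47.2 to 132), the sarcomere giant Ttn 38.3-fold, the triadin gene Trdn 28.0-fold and the muscle mutase Pgam2 20.3-fold. The extracellular protein cochlin, Coch, was 123-fold higher (12.6 against 1546 CPM) and the WNT inhibitor Wif1 22.6-fold. In EKP fibroblast-like cells Ptn was 7.75-fold higher (6.65 to 9.10), opposite to the Krt8-rich cells, beside Ctla2a (3.43-fold), Ecrg4 (3.15-fold), Cd5l (at least 4.85-fold), Nnat (at least 3.94-fold) and Mpo (at least 3.39-fold). The core fibroblast genes lay close: Col1a1 had a ratio of 0.978, Lum 1.18, Mmp2 0.836 and Dpt 0.722. Of 216 kept genes, 55 were at least 2-fold higher in RKP and 10 in EKP, over 15827 and 8926 cells of EKP and RKP, and none of 13 lists lay outside the random range. Within that range, some lists of other cell types had members higher in RKP and none higher in EKP. They were the T cell (3 of 3, median log2 1.77), checkpoint (3 of 4, 1.52) and endothelial (2 of 4, 1.53) lists. Whether neighbouring cells gave these transcripts was not tested. At 1000 CPM or more, 15 genes were 2-fold apart, and with each section clustered by itself 143.

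T cell-like cells of the RKP section stood at 1.60 times the EKP level of Ctla4 and 1.37 times that of Pdcd1, both checkpoint receptors, and at 1.15 times that of the granzyme Gzmb and 0.931 times that of Cd8a, values under 2-fold. Prf1, the pore-forming perforin of cytotoxic cells, was 2.10-fold higher in EKP. The genes with the largest ratios were not T cell genes: the mast cell gene Cpa3 (10.7-fold, 8.39 to 13.99), Cyp11a1 (10.1-fold), Ttn (6.48-fold), Muc13 (5.19-fold) and Mmrn1 (19.5-fold, from 4 counts in EKP) were higher in RKP, and Pvalb was at least 10.1-fold higher. Mpo, of neutrophil granules, was 60.9-fold higher in EKP (23.0 to 228, from 4 counts in RKP), with Ctsg (6.49-fold, 1.56 to 38.0) and Abca13 (10.5-fold, 2.90 to 57.7) resting on 3 counts each in RKP, a level within the background, Fcnb on 16 against 2 counts, and Ccn3 and Chga 3.62-fold and 3.87-fold higher. Of 13 lists, the proliferation list (median 0.29, with no member past 2-fold) and the mural list (0.83) lay above the random range and the matrix (-0.45) and fibroblast (-0.53) lists below. In total 38 of 160 kept genes were 2-fold apart, 19 each way, over 1770 EKP and 4578 RKP cells. The count was 16 with cells of 40 or more counts, 117 with finer clusters, 94 with each section clustered by itself and 12 at 1000 CPM or more. With cells of 40 or more counts, most cells called T cell-like had no Cd3e count. The same held for RKP with finer clusters and for EKP with each section clustered by itself.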

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

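Tests chosen only after the result was seen were those of shallow-cell signal and of scaling for the EKP genes, that of Krt5 away from the squamous cluster, and that of Trp53 in cluster 14; the Epcam split and the limit of 1000 CPM were also chosen then.

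Some counts lay outside the gene comparisons. Negative control probes, which should give no counts, summed to 1583 in EKP and 696 in RKP, negative control codewords to 2760 and 3327, and the unassigned codeword to 39 and 20. They are listed because they exceed the 3 counts that a count of 0 allows, a rule that tests nothing about their source. A single negative control codeword held 1897 of the codeword counts in EKP and 2373 in RKP, and the next one held 105 and 157. Cells with under 20 counts, left out of the clustering, held 673795 gene counts in EKP and 90531 in RKP.

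Of 443 genes kept in both the Epcam-high and the Epcam-low clusters, 17 had opposite ratios, each at least 2-fold. Of the 175 with at least 1000 CPM in either group of clusters, 5 did. As log2 of RKP over EKP, the ratios were 1.04 and -1.64 for the water and glycerol channel Aqp3, 1.09 and -1.34 for Cavin2, a protein of caveolae, and 1.12 and -1.12 for Ctla2a. They were -1.04 and 1.78 for the EGF receptor ligand Areg, and -1.05 and 3.45 for Hey1. The difference was not tested, since each group had 1 section.

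The first pattern is the set of 152 genes, among them 8 of kidney and 8 of brain, that were 2-fold or more higher in EKP and under 1000 CPM. Genes of kidney, liver, brain and airway were found together in EKP cells 1.34 times as often as chance gives (median of 4 lists). T cell genes reached 10.7 times. By the limits set beforehand this argued against stray cells of other organs. Muscle genes, which led a cluster, reached only 1.94 times in EKP and 4.15 times in RKP, under the limit set for an organ's cells. The comparison can thus miss real tissue and does not decide. Scaling moves every gene alike, and the 176 genes with at least 1000 CPM had a median EKP over RKP ratio of 0.977. Scaling to the total holds abundant genes near 1, so that value cannot decide either. As counts per cell and by median of ratios, 133 and 137 genes stayed at least 2-fold higher in EKP, against 166. That argues against scaling as the whole cause. Enrichment in injected cells holds for few: among EKP cells with 160 or more counts, 16 genes were 2-fold higher in Krt8-rich than in other cells. Expression by injected cells does not require such enrichment. Within Krt8-rich cells of that depth, 75 of the 152 were 2-fold higher in EKP than in RKP, so the 16 do not decide. The low-count cluster with high Krt8 was not counted as Krt8-rich here, although its leading genes all belong to the set. In EKP, the set's median gene took a 104-fold higher share of counts in cells under 20 counts than in those with 160 or more. The negative control probes also rose, 39.8-fold over pooled counts, a measure unlike a median over genes. So non-specific signal in shallow cells may account for much of the set, but not for the whole, since 84 of 152 genes stayed 2-fold higher in cells with 160 or more counts, where the median ratio was 2.18 and not 7.27. What the remaining signal is stays open, and a difference between the tumour lines or in tissue quality was not separable with 1 section each.

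The second pattern is the squamous cluster with 4187 RKP and 3 EKP cells. With cells thinned to 40 counts before clustering, the class held 5613 RKP and 2359 EKP cells. After thinning, Krt5 was detected in only 266 EKP cells, against 4527 RKP cells. Most EKP cells of that class thus had no Krt5 count, and what they are was not tested. A shift of the whole RKP library is argued against as the whole cause, because Krt5 was 4.00-fold higher in RKP outside the cluster (35.7 against 142.8 CPM) and 1.63-fold in the 83 of 100 parts of the RKP file with almost no such cells, set against all of EKP, not 13.8-fold. What the remaining ratio is stays open. Fibroblast-like cells near these cells in the file order, which partly follows place in the tissue (39.7% of EKP and 37.3% of RKP cells had a next cell of the same cluster, against 9.97% and 10.4% by chance), were at 4.89 times their share of the section, so skin of the host in the section is a candidate explanation. A squamous state of the injected cells cannot be told apart from it, because Krt8-rich cells near them were at 0.796 times their share, between the limits set for either reading, and the clusters behind that value parted. The Epcam-low clusters were at 2.23 and 0.744 times, and the Epcam-high ones at 0.00729, 0.00979 and 0.272. Unnamed clusters parted as well, with no limit set for them. That with macrophage and fibroblast genes was at 4.28 times, that led by muscle genes at 3.72 and the low-count one with high Krt8 at 3.67. Those with mural and fibroblast genes and with epithelial and macrophage genes were at 0.0442 and 0.0126. Trp53 stood at 5149 CPM in the squamous cluster, against 1441 in the highest Krt8-rich cluster. Krt8 stood at 396 CPM, the lowest of all clusters. The Trp53 limit used for cluster 14, chosen after the result was seen, would read this level against injected cells. No limit was set for this cluster, and the values rest on 1 section, so the question stays open.

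The third pattern is cluster 14, with 11067 RKP and 15 EKP cells, led by Ambp, Tm4sf4, Sftpd, Muc3a, Agr2 and the trefoil peptide Tff2. A shift of the whole RKP library is argued against, since Ambp outside the cluster was 1.15-fold higher in RKP. Host glandular tissue cannot be fully told apart from a state of the injected cells. Fibroblast-like cells near cluster 14 in the file order were at 0.0556 times their share, against 4.89 times near the squamous cluster. No limit was set for that value. The other Krt8-rich cells near cluster 14 were at 1.44 times their share, a value set beforehand to argue against host tissue. That limit took the Krt8-rich clusters as 1 group, but they parted: the Epcam-low ones were at 2.46 and 2.29 times and the Epcam-high ones, under their share, at 0.771 and 0.691. None of these was low enough to meet the limit set for host tissue, while the Epcam-high ones lay between both limits. The pooled value thus goes against host tissue, but the Epcam-high clusters taken alone do not decide. Trp53 stood at 362 CPM in the cluster, 0.251 times (0.232 to 0.272) the highest other Krt8-rich cluster, as a state of the injected cells would allow. A host gland with low Trp53 would meet that limit too. The labels do not give the Trp53 state of the lines, and the probe positions are not known. The Trp53 level thus does not decide. A secretory state of part of the injected RKP cells may account for cluster 14, as a hypothesis found and tested on the same section. Host gland is not excluded.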

How the results depend on the processing

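The alternatives with a 1000 CPM limit, cells of 80 or more counts, shares without low-count clusters and the mixed cluster counted as immune were chosen after the data were seen. No paired analysis was possible because each group held 1 section, and none of the values comes from a test. A count of genes, lists or classes was taken as kept within 1.5-fold of its main value, and a share difference only inside the outer limits of both 95% intervals, so shares moved more readily. Under the alternatives fixed in advance, 43 values of the main results were kept so, 21 moved and 1 was reversed; of those added later, 3 kept and 11 moved; for the shares of single classes 7 kept, 28 moved and 4 were reversed. The immune share difference was 3.03 and 7.08 points with cell filters of 10 and 40 counts (the first with an NK class of 5.56% of EKP and 0.416% of RKP cells, led by Hsd3b4), 7.76 and 8.61 at resolutions 0.5 and 2, 8.48 after thinning, 2.71 without low-count clusters, 2.10 with the mixed cluster, and -17.1 with each section clustered by itself, where T cell-like and macrophage-like shares also turned to -6.42 and -9.47 points. Most EKP cells called T cell-like by separate clustering had no Cd3e count. The same held for most RKP cells called so at resolution 2. It also held for most cells of both sections called so with the filter of 40 counts. The neutrophil-like share turned to 0.0373 and 0.150 points at resolutions 0.5 and 2, where 2 and 3 classes were 1.5-fold apart and not 5. Genes higher in RKP numbered 83 as counts per cell, 68 by median of ratios, 24 with cells weighted alike, 16 at 1000 CPM and 81 in cells of 80 or more counts; the last limits gave 14 and 92 genes higher in EKP, and with cells alike 3 lists lay outside. Within Krt8-rich cells, 1000 CPM left 23 and 11 genes, and the EKP count was 159 at resolution 2 and 181 by separate clustering. At 1000 CPM, 4 macrophage-like, 15 fibroblast-like and 12 T cell-like genes were 2-fold apart. Separate clustering gave 59, 143 and 94 for the same classes. For macrophage-like cells the count was 6 with cells alike, 85 with 40 or more counts and 117 after thinning; for T cell-like cells it was 16 with 40 or more counts and 117 at resolution 2. No cluster was named T cell at resolution 0.5 or after thinning, or fibroblast at resolution 0.5, so these gave no value. A limit of 1000 CPM admits fewer genes by construction, and counts per cell and median of ratios shift every log2 ratio alike. For the other moves the cause was not tested. Depth limits EKP most, since 26.6% of its cells had under 20 counts.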

Other observations

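Each gene and cluster named from here on was chosen after its values were seen.

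Endothelial-like cells were left out of the comparisons, and no list of lymphatic genes was tested. Prox1, the transcription factor of lymphatic identity, was 17.9-fold higher in RKP (15.4 to 20.8; 71.8 against 1282 CPM), and Mmrn1, a protein of lymphatic endothelium, 19.6-fold (17.8 to 21.6; 166 against 3239 CPM). The muscle genes Ttn and Pvalb were 25.02-fold and 55.1-fold higher. In EKP endothelial-like cells Aqp7 was 3.32-fold and Slc14a1 2.05-fold higher. Of 137 kept genes, 23 were at least 2-fold higher in RKP and 4 in EKP, over 16110 EKP and 14809 RKP cells.

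An unnamed cluster with low counts, led by muscle genes such as Pvalb, Pgam2, Ttn and Trdn, held 8600 EKP and 1005 RKP cells, with median counts of 25 and 49. Muscle genes were found together in the same cells 1.94 times as often as chance gives in EKP and 4.15 times in RKP. Another low-count unnamed cluster, led by Kcna1, Hsd3b4 and Scg2, held 23237 EKP and 1569 RKP cells. An unnamed cluster that combined epithelial genes with Ccl9, Arg1 and Mmp8 held 1347 EKP and 10329 RKP cells. Macrophage-like cells fell into a cluster shared by the sections (15240 EKP and 24526 RKP cells) and a cluster led by Mmp8 and Ccl9 that held 1101 EKP and 13034 RKP cells.

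The Krt8-rich clusters were nearly split by section. The Epcam-high cluster led by Cldn2, Gabrp and Muc20 held 874 EKP and 53483 RKP cells, and that led by Ivl, Gpx2 and Snap25 held 32348 EKP and 5694 RKP cells. The Epcam-low cluster led by Ptn held 1112 EKP and 36735 RKP cells, and that led by the endocytic receptor Lrp2 held 14980 EKP and 2909 RKP cells. Across 175 genes with at least 1000 CPM in either group of clusters, 37 were at least 2-fold higher in Epcam-low than in Epcam-high cells in both sections, 30 were lower in both and 1 was opposite.

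Neutrophil-like cells had median counts of 48 in EKP and 72 in RKP. They pooled a cluster of 14797 EKP and 10090 RKP cells with one of 4944 and 12547. In them 188 of 279 kept genes were at least 2-fold higher in EKP and 5 in RKP, with the potassium channel gene Kcnj16 and Hsd3b4, both in the set of EKP genes under 1000 CPM, at 30.3-fold and 27.7-fold. Among genes with at least 1000 CPM, 9 were higher in EKP and 4 in RKP.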
